A study of Mus musculus with 16 samples.

How the data were processed

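Whole dorsal skin from 16 samples (male, 8 weeks, telogen, per the labels) was sequenced as 4 libraries in each of 4 groups, WT or Tnfrsf1a and Tnfrsf1b double knockout, each without UVB (control) or after 3xUVB. Per the labels' protocols, skin was frozen in liquid nitrogen, total RNA was extracted with Trizol, and poly(A)-enriched directional libraries were made with a NEBNext Ultra II kit. Per the submitters' processing notes, reads were aligned to GRCm39 with STAR, whose version and annotation release are not given in the sources used here. The deposited values of each library are raw read counts per gene as written by STAR, per the submitters' processing notes and the layout of the columns, which have no header: an unstranded count and counts for each strand. The authors' summed lines for unmapped, multimapping, no-feature and ambiguous reads were kept out of library sizes and tests. They held 10.7 to 19.5% (unmapped), 7.25 to 10.2% (no feature) and 1.18 to 1.42% (ambiguous) of each library's reads, and 0 reads on the line for multimapping. A combined count table of the series has no header that assigns its 17 value columns to samples, and these columns are not used here.

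Reads on the reverse strand made up 95.74% of the forward and reverse counts, and the reverse-strand column was used under a rule set at 80%. The files hold 55359 gene IDs. Names came from a GENCODE annotation of another genome build, which was used for gene names and gene order alone and gave symbols to 52083 IDs, leaving 1.23% of reads in unnamed IDs. Statements on genes next to Tnfrsf1a and Tnfrsf1b rest on that gene order. With filterByExpr, 17531 genes were tested, which held 99.9% of the reads in genes. Depth was 15644375 to 23200649 reads in genes, with antisense reads at 3.91 to 5.25%, mitochondrially encoded reads at 1.69 to 2.52% and the 10 most abundant genes at 6.59 to 10.9%. TMM factors were 0.940 to 1.07. The common biological coefficient of variation was 0.18.

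Counts were fitted with edgeR 4.0.16 (quasi-likelihood, robust, TMM) in R 4.3.3 as 1 model of the 4 groups. The 5 contrasts were UVB against control in WT, UVB against control in KO, KO against WT without UVB, KO against WT with UVB, and the interaction of these, the UVB effect in KO minus that in WT. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast, and log2 fold changes are those of the edgeR fit. Log2 CPM, used for the list tests, list scores and principal components, have a prior count of 2. CPM are TMM-normalised. The standard error is that of the log2 fold change implied by the test. The groups, contrasts, lists, naming rule and most alternatives were set before the data were examined, and the text says where a choice came after.

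Genes are named by a rule. In each comparison it takes Tnfrsf1a and Tnfrsf1b, then the 8 higher and 8 lower called genes with the largest change among those with a mean count of at least 50, no overlap of CPM between groups (not asked of the interaction) and a symbol that is not a predicted gene or clone name. It adds the 3 members with the smallest adjusted p among the called genes of each called list, and always Mitf, Kit, Dct, Tyr, Tyrp1, Pmel, Mlana, Sox10, Kitl, Tnf, Il1b, Il6, Cdkn1a, Krt6a, Mki67 and Tgfb2. The report names part of these. No fold change is given against a group with 3 counts or fewer in total, and setting such genes to a floor of 3 counts over the group changed no list median.

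The 32 gene lists, written from general knowledge of the genes and tested with at least 5 measured members, were melanocyte lineage and pigmentation, melanocyte niche signals, Wnt pathway, TNF receptor pathway components, NF-kB target genes, epidermal alarmins and IL-1 family, type I interferon response, p53 and DNA damage response, cell death pathways, oxidative stress response, cell cycle and proliferation, stress and wound keratinocyte genes, epidermal terminal differentiation, basal keratinocyte and hemidesmosome, anagen hair follicle, hair follicle bulge stem cell, neutrophil, monocyte and macrophage, Langerhans and dendritic cell, T and NK cell, B and plasma cell, mast cell, skeletal muscle, adipocyte, dermal fibroblast and matrix, matrix proteases and plasminogen system, endothelial, sebaceous gland, Schwann and nerve, erythrocyte, immediate early and heat shock, and mitochondrially encoded. Each was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 32 lists. Alternatives were camera with a correlation estimated for each list, fry, and a two-sided exact permutation of list scores, whose smallest possible p is 0.0286 with 4 against 4 libraries. A list score is the mean of its members' standardised log2 CPM in a library.

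Alternatives for the gene tests were DESeq2 1.42.0, limma voom with sample quality weights, DESeq2 size factors or library totals in the edgeR fit, no filter beyond 1 read, a mean count of at least 100, the unstranded counts, a fit of the 2 groups alone, the sample numbers as a block, the skeletal muscle score as a covariate and each library left out in turn. Added after seeing the data were the anagen hair follicle score as a covariate and leaving out KO UVB libraries 3 and 4 together.

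The tests were first run on simulated counts of 17279 genes with the libraries' means and depths. For UVB in WT, 23.5, 69.7 and 90.9% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 8 false calls (6.15% of calls). The genes changed numbered 68, 66 and 66, against 3290 called for UVB in WT in the data. Adjustment is stricter with fewer changed genes, so these shares do not give the recovery of the real UVB test. For KO against WT with UVB the shares were 25.0, 68.2 and 92.4% with 6 false calls (4.65%), and for the interaction 7.35, 53.0 and 87.9% with 9 false calls (8.41%). A list of 28 members raised by 0.5 was called and 0 other lists were. The simulated genes were drawn independently of each other, so these runs do not measure false list calls among genes that vary together.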

Results

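Whole dorsal skin of male mice aged 8 weeks, labelled as telogen (the resting phase of the hair cycle), was profiled by RNA sequencing. Wild-type mice (WT) were set beside mice in which both TNF receptor genes, Tnfrsf1a and Tnfrsf1b, were knocked out (KO). Skin of each genotype was taken without UVB (control) or after a treatment labelled 3xUVB (UVB), whose dose and timing are not given in the sources used here. The 4 groups, WT control, WT UVB, KO control and KO UVB, held 4 libraries each, with 15644375 to 23200649 reads in genes per library. On the first principal component of log2 CPM, 44.5% of the variance, all control libraries lay on one side and all UVB libraries on the other. The series title places the work in the question of how deficient Tnf signalling bears on melanocyte stem cells of UVB-exposed skin. Values after a gene symbol are log2 fold changes ± SE with adjusted p from edgeR's quasi-likelihood test, or normalised counts scaled to library size (CPM) as mean ± SD, with n = 4 per group. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these samples. In the 24 pairs of libraries within a group, counts differed by a chi-square of 14.3 to 151 per degree of freedom. These values argue against repeated sequencing of the same library. Separate skin pieces or preparations from the same animal stay open, so part of the spread may be technical.

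Transcripts of both targeted receptor genes were lower in KO skin and still present. Tnfrsf1a (ENSMUSG00000030341.18), which encodes TNF receptor 1, was at 143 ± 6.67 CPM in WT control and 151 ± 8.87 in WT UVB skin, against 85.9 ± 5.42 in KO control and 95.8 ± 6.78 in KO UVB skin. Tnfrsf1b (ENSMUSG00000028599.11), which encodes TNF receptor 2, was at 57.8 ± 13.4 CPM in WT control and 40.9 ± 7.99 in WT UVB skin, against 20.8 ± 4.17 and 20.1 ± 5.54 in KO control and KO UVB skin. The highest KO library lay below the lowest WT library for both genes, at 105 against 133 CPM for Tnfrsf1a and at 27.9 against 33.6 CPM for Tnfrsf1b. Raw counts in the KO libraries were 1495 to 2270 for Tnfrsf1a and 274 to 604 for Tnfrsf1b. Which part of each gene the knockout alleles lack is not given in the sources used here, and counts per gene cannot show it. In KO against WT control skin Tnfrsf1a (-0.74 ± 0.07, adjusted p = 5.43e-05) and Tnfrsf1b (-1.47 ± 0.21, adjusted p = 0.00206) both fell. With UVB, Tnfrsf1a (-0.66 ± 0.07, adjusted p = 0.000152) and Tnfrsf1b (-1.02 ± 0.21, adjusted p = 0.0315) also fell in KO against WT. The Tnfrsf1b call with UVB ended without WT UVB library 1 (adjusted p = 0.0886), 3 (0.0594) or 4 (0.0607) and without KO UVB library 2 (0.0892), and its adjusted p ran from 0.000379 to 0.0946 over all alternatives. UVB against control gave 0.08 ± 0.07 for Tnfrsf1a in WT (adjusted p = 0.453) and 0.16 ± 0.07 in KO (0.106). It gave -0.50 ± 0.21 for Tnfrsf1b in WT (0.102) and -0.05 ± 0.21 in KO (0.878), so that no UVB effect on either gene passed the test.

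**Figure D1:**
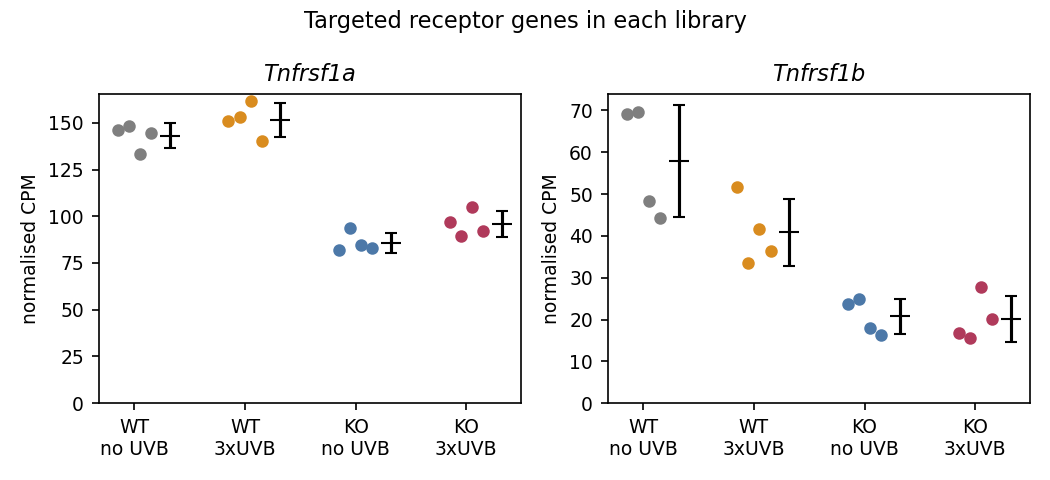
Normalised CPM of Tnfrsf1a and Tnfrsf1b in each of the 16 libraries by group, with each point 1 library and the black mark and bar the mean and SD (n = 4). The highest KO library, 105 CPM for Tnfrsf1a and 27.9 CPM for Tnfrsf1b, lies below the lowest WT library, 133 and 33.6 CPM.

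In WT skin after UVB, genes of the cornified epidermis, of proliferation and of the p53 response were higher and genes of the growing hair follicle lower. Flg, which encodes the cornified layer protein filaggrin, rose from 87.4 ± 19.9 to 1354 ± 179 CPM (3.95 ± 0.34, adjusted p = 6.63e-06). Padi3, an enzyme that citrullinates hair shaft proteins, fell from 25.8 ± 11.2 to 0.825 ± 0.813 CPM (-4.94 ± 0.55, adjusted p = 3.99e-05). Among the genes with the largest changes were Stfa3, a stefin-family protease inhibitor (6.12 ± 0.76, adjusted p = 9.35e-05), Saa3, an acute-phase serum amyloid A (6.08 ± 1.15, adjusted p = 0.00227), and Olah, a fatty acyl thioesterase (6.64 ± 0.74, adjusted p = 4.13e-05). Of 17531 genes tested, 3290 were called, 1782 higher and 1508 lower, and 929 of the calls exceeded 2-fold. In 3017 of the called genes the 4 UVB and 4 control libraries did not overlap, and over all tested genes 28.2% did not overlap, where chance gives 2.86%. Without WT control library 1 the count was 2039 and without WT UVB library 3 it was 2147. Added after seeing the data, a fit with each library's anagen hair follicle score as a covariate called 1 gene. That score is built from the list's own genes and separates the groups, at a mean of 1.33 in WT control and -0.57 in WT UVB libraries, so this fit compares the groups with little of their difference left.

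Of the 32 gene lists fixed before the data were examined, camera called 12 in WT, 6 higher and 6 lower. Each of the 12 calls was lost with an estimated correlation, and that p stands beside each list. The epidermal terminal differentiation list rose (23 of 28 members rose, 23 rose adjusted over the list alone), with the cornified envelope genes Lce1f (3.36 ± 0.24) and Lce1a1 (1.81 ± 0.17) beside Flg. The median was 1.36 (camera adjusted p = 2.82e-20, adjusted p = 0.11 with an estimated correlation). The list of stress and wound keratinocyte genes rose (14 of 24 members rose, 15 rose adjusted over the list alone), led by the kallikrein proteases Klk6 (1.89 ± 0.22) and Klk13 (3.83 ± 0.46) and the protease inhibitor Serpinb3a (5.81 ± 0.73). Its median was 1.59 (camera adjusted p = 1.12e-08, adjusted p = 0.298 with an estimated correlation). In the list of epidermal alarmins and IL-1 family genes (7 of 17 members rose and 1 fell, 9 rose and 1 fell adjusted over the list alone), the interleukin-36 genes Il1f6 (5.18 ± 0.61), Il1f8 (3.33 ± 0.36) and Il1f9 (2.07 ± 0.24) rose. Members had a median of 1.11 (camera adjusted p = 0.000283, adjusted p = 0.373 with an estimated correlation). Proliferation genes rose together (22 of 28 members rose, 24 rose adjusted over the list alone), among them Rrm2, a subunit of ribonucleotide reductase (1.02 ± 0.11), and the cyclins Ccne2 (0.90 ± 0.14) and Ccnb1 (1.40 ± 0.26). Over the list the median was 0.95 (camera adjusted p = 1.21e-13, adjusted p = 0.327 with an estimated correlation). The p53 and DNA damage list rose (13 of 26 members rose and 2 fell, 15 rose and 2 fell adjusted over the list alone), with the cell cycle inhibitor Cdkn1a at 153 ± 13.8 and 322 ± 17.5 CPM (1.08 ± 0.10), the proapoptotic gene Pmaip1 (1.14 ± 0.12) and the kinase gene Plk3 (0.97 ± 0.10). This list's median was 0.29 (camera adjusted p = 2.65e-05, adjusted p = 0.11 with an estimated correlation). Sebaceous gland genes rose (6 of 17 members rose, 10 rose adjusted over the list alone), including the fatty acid elongases Elovl3 (2.15 ± 0.28) and Elovl4 (1.28 ± 0.20). Here the median was 0.58 (camera adjusted p = 9.96e-05, adjusted p = 0.333 with an estimated correlation).

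Lower after UVB in WT were hair, nerve, blood and lymphocyte lists. Anagen hair follicle genes fell (22 of 23 members fell, 22 fell adjusted over the list alone), with the hair cuticle gene S100a3 (-4.45 ± 0.42), the crystallin-family gene Crym (-2.90 ± 0.26) and Padi3. The median was -5.04 (camera adjusted p = 1.97e-22, adjusted p = 0.11 with an estimated correlation). WT UVB library 2 held more of these transcripts than its group, with a list score of 0.0486 against -0.840 to -0.734 in the others. The skin is labelled telogen, yet WT control libraries held 684 to 1295 reads of Krt72, a member of this list, against 0 to 102 after UVB. Whether hair cycle stage differed between control and UVB skin was not tested. The Schwann and nerve list fell (9 of 15 members fell, 11 fell adjusted over the list alone), including the myelin gene Prx (-0.75 ± 0.14) and the cadherin gene Cdh19 (-1.09 ± 0.14). Its median was -0.61 (camera adjusted p = 1.15e-05, adjusted p = 0.287 with an estimated correlation). T and NK cell genes were called lower (1 of 22 members rose and 8 fell, 1 rose and 8 fell adjusted over the list alone): Trdc, the constant segment of the delta T cell receptor chain (-1.59 ± 0.20), and Cd247 (-1.18 ± 0.24) fell, while Trbc2, a beta chain constant segment, rose (0.57 ± 0.13). Members had a median of -1.01 (camera adjusted p = 0.00454, adjusted p = 0.719 with an estimated correlation). B and plasma cell genes fell (4 of 6 members fell, 5 fell adjusted over the list alone), with the immunoglobulin genes Igkc (-2.62 ± 0.58) and Jchain (-2.32 ± 0.56). Over the list the median was -1.46 (camera adjusted p = 0.00262, adjusted p = 0.18 with an estimated correlation). The erythrocyte list fell (3 of 8 members fell, 5 fell adjusted over the list alone), led by the alpha globin gene Hba-a2 at 13.3 and 0.0875 CPM (-7.17 ± 0.61), whose reads a near-identical copy can take. This list's median was -0.68 (camera adjusted p = 0.000896, adjusted p = 0.298 with an estimated correlation). The Langerhans and dendritic cell list was called lower (2 of 20 members fell, 1 fell adjusted over the list alone), with the dendritic cell growth factor receptor Flt3 (-0.61 ± 0.13). Here the median was -0.39 (camera adjusted p = 0.0297, adjusted p = 0.801 with an estimated correlation).

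Melanocyte genes did not move together after UVB in WT skin. In the melanocyte lineage and pigmentation list (1 of 17 members rose and 4 fell, 1 rose and 4 fell adjusted over the list alone, median -0.07, camera adjusted p = 0.613), the lineage transcription factors Mitf (-0.49 ± 0.12, adjusted p = 0.00871) and Sox10 (-0.67 ± 0.15, adjusted p = 0.00533) and the receptor Kit (-0.43 ± 0.11, adjusted p = 0.0178) fell. The melanosome genes Dct (0.31 ± 0.26), Tyr (0.03 ± 0.42), Tyrp1 (0.05 ± 0.33), Pmel (0.48 ± 0.27) and Mlana (0.41 ± 0.30) did not pass the test, nor did Kitl, the ligand of Kit (0.13 ± 0.10), or Tnf (-0.63 ± 0.46). Sox10 also marks Schwann cells and Kit mast cells. The Kit call ended without WT control library 1 (adjusted p = 0.061) or WT UVB library 2 (0.0515) or 3 (0.0686), within 0.0032 to 0.754 over all alternatives. The proliferation marker Mki67 (0.88 ± 0.25, adjusted p = 0.0248) was no longer called without WT control library 2 (0.0764) or 4 (0.071) or WT UVB library 2 (0.0576) or 4 (0.0543), within 0.00134 to 0.746 over all alternatives.

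The other 19 lists were not called in WT. Among skin and follicle lists, hair follicle bulge stem cell genes had a median of -0.34 (3 of 15 fell), basal keratinocyte and hemidesmosome genes 0.06 (3 rose, 1 fell), melanocyte niche signals -0.26 (4 fell) and Wnt pathway genes -0.12 (2 rose, 4 fell). Among stress and inflammation lists, the oxidative stress response had a median of 0.25 (5 of 16 rose), cell death pathways 0.05 (3 rose, 1 fell), immediate early and heat shock genes 0.22 (3 rose, 1 fell), NF-kB target genes -0.05 (1 fell), TNF receptor pathway components -0.04 (1 of 22 rose) and matrix proteases and the plasminogen system 0.22 (2 rose, 2 fell). The type I interferon list had a median of -0.04 over 27 members, and edgeR, DESeq2 and limma voom each called 0 of them, as did an unadjusted p under 0.05. Among cell type lists, the median was 0.48 for neutrophils (3 rose, 1 fell), -0.42 for monocytes and macrophages (1 fell), -0.28 for mast cells (2 fell), -0.16 for endothelium (1 fell), -0.37 for adipocytes (1 rose), -0.13 for skeletal muscle (1 fell), -0.02 for dermal fibroblasts and matrix (1 fell) and 0.03 for mitochondrially encoded genes (1 rose). Camera adjusted p ran from 0.0555 to 0.982 over these lists. Adjusted over the list alone, the counts were 5 rose and 1 fell for oxidative stress, 2 rose and 6 fell for Wnt and 3 rose and 2 fell for matrix proteases, and the single falls of the NF-kB, monocyte, endothelial and fibroblast lists no longer passed. The test pointed up against a negative median in the TNF receptor pathway and interferon lists, and the mean was above 0 against a negative median in the interferon and NF-kB lists.

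**Figure D2:**
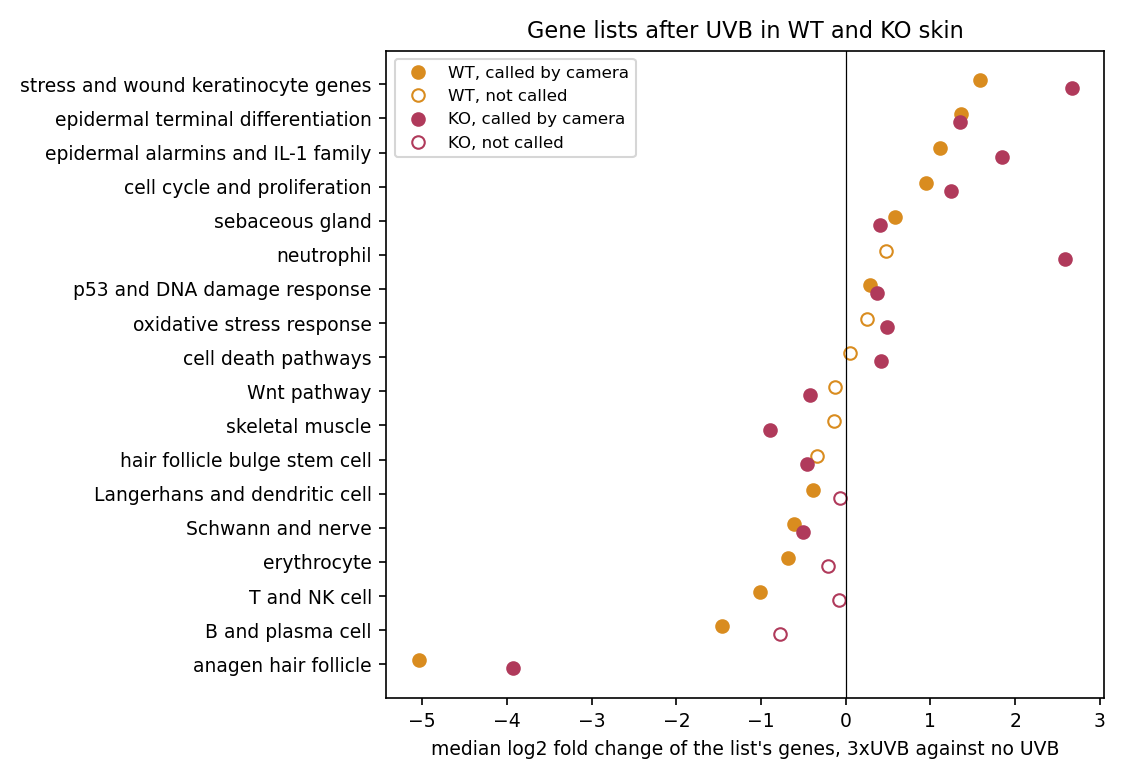
Median log2 fold change (x axis), 3xUVB against control, of each gene list (y axis) that camera called in WT or KO skin, with filled points for called lists and open points for lists not called. Epidermal, stress keratinocyte, alarmin and proliferation lists lie to the right of 0 in both genotypes, and the anagen hair follicle list lies farthest to the left, at -5.04 in WT and -3.93 in KO.

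In KO skin after UVB, epidermal, alarmin, proliferation, stress keratinocyte and neutrophil genes were higher, and skeletal muscle and hair follicle genes lower. Krt6a, a keratin of wounded and hyperproliferative epidermis, rose from 112 ± 30.0 to 1308 ± 719 CPM (3.55 ± 0.45, adjusted p = 7.73e-05), with KO UVB library 4 at 237 CPM and the other 3 between 1598 and 1775. Spink7, a Kazal-type protease inhibitor, was at 0.026 CPM in KO control and 28.0 ± 22.9 CPM in KO UVB skin, too few control counts for a fold change. Sprr1b, a cornified envelope precursor, rose (5.16 ± 0.79, adjusted p = 0.000347), as did Serpinb3a (6.04 ± 0.71), Stfa3 (5.18 ± 0.71) and Olah (7.56 ± 0.78). The hair keratin genes Krt33a (-5.43 ± 0.93, adjusted p = 0.000679) and Krt72 (-5.84 ± 1.33) were among those that fell most. In all, 5666 genes were called, 3011 higher and 2655 lower, 1319 of them beyond 2-fold. The groups did not overlap in 3954 of the called genes and in 25.1% of all genes tested, where chance gives 2.86%. Leaving out 1 library gave 4280 to 6350 calls and leaving out KO UVB libraries 3 and 4 together, a setting added after seeing the data, gave 5620, while a fit of these 2 groups alone gave 3506. Also added after seeing the data, the anagen score as a covariate gave 319 calls, with mean scores of 0.14 in KO control and -0.90 in KO UVB libraries.

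Camera called 14 lists in KO, 9 higher and 5 lower, each lost with an estimated correlation. All 28 members of the proliferation list rose, with Rrm2 (1.24 ± 0.11), Ccne2 (1.07 ± 0.14) and the mitotic survivin gene Birc5 (1.60 ± 0.24) (28 rose adjusted over the list alone, median log2 fold change 1.25, camera adjusted p = 4.47e-15, adjusted p = 0.28 with an estimated correlation). Stress and wound keratinocyte genes rose (20 of 24 members rose, 22 rose adjusted over the list alone), including Klk6 (2.44 ± 0.22) and Klk13 (4.07 ± 0.45). The median was 2.67 (camera adjusted p = 2.46e-12, adjusted p = 0.28 with an estimated correlation). Alarmins rose (14 of 17 members rose, 14 rose adjusted over the list alone), with the cytokine Il1a (1.54 ± 0.18), the antimicrobial beta-defensin Defb14 (3.35 ± 0.41) and Il1f8 (3.59 ± 0.36). Its median was 1.85 (camera adjusted p = 1.49e-07, adjusted p = 0.28 with an estimated correlation). Epidermal terminal differentiation genes rose (21 of 28 members rose and 2 fell, 21 rose and 3 fell adjusted over the list alone), with Flg (3.64 ± 0.34), Lce1f (3.04 ± 0.24) and the transglutaminase Tgm3 (3.00 ± 0.31). Members had a median of 1.35 (camera adjusted p = 6.55e-10, adjusted p = 0.28 with an estimated correlation). The p53 list rose (13 of 26 members rose and 3 fell, 16 rose and 3 fell adjusted over the list alone), with Cdkn1a (0.95 ± 0.10), Pmaip1 (1.42 ± 0.12) and Plk3 (0.92 ± 0.10). Over the list the median was 0.37 (camera adjusted p = 0.000251, adjusted p = 0.28 with an estimated correlation). Neutrophil genes rose (10 of 13 members rose and 1 fell, 11 rose and 1 fell adjusted over the list alone), among them the neutrophil collagenase Mmp8 (3.05 ± 0.41) and the chemokine receptor Cxcr2 (3.71 ± 0.66), which was at 31.7 CPM in KO UVB library 3 and at most 7.42 in the others. This list's median was 2.60 (camera adjusted p = 0.000647, adjusted p = 0.323 with an estimated correlation). Oxidative stress genes rose (10 of 16 members rose, 10 rose adjusted over the list alone), with the glutathione transferase Gsta4 (2.22 ± 0.31) and sulfiredoxin Srxn1 (0.80 ± 0.13). Here the median was 0.49 (camera adjusted p = 0.00229, adjusted p = 0.28 with an estimated correlation). In the cell death list (9 of 23 members rose and 1 fell, 9 rose and 1 fell adjusted over the list alone), the pore-forming gasdermins Gsdma (1.49 ± 0.14) and Gsdmc (3.79 ± 0.45) rose and the survival gene Bcl2 fell (-0.58 ± 0.11). The median was 0.41 (camera adjusted p = 0.00633, adjusted p = 0.484 with an estimated correlation). Sebaceous gland genes were called higher (9 of 17 members rose and 1 fell, 9 rose and 1 fell adjusted over the list alone), with Elovl3 (2.21 ± 0.28) higher and the desaturase Scd3 (-1.38 ± 0.28) lower. Its median was 0.40 (camera adjusted p = 0.00953, adjusted p = 0.547 with an estimated correlation).

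Muscle, hair and nerve lists were lower after UVB in KO skin. Skeletal muscle genes fell (15 of 20 members fell, 18 fell adjusted over the list alone), among them the sarcomere genes Neb (-1.20 ± 0.14), Ttn (-1.16 ± 0.15) and Actn3 (-1.66 ± 0.35). Members had a median of -0.89 (camera adjusted p = 1.39e-06, adjusted p = 0.37 with an estimated correlation). KO control library 1 was the highest in Actn3, at 1125 CPM against 424 to 513 in its group. With each library's muscle score as a covariate, Actn3, which is part of that score (-0.43, adjusted p = 0.274, within 7e-06 to 0.274 over all alternatives), was no longer called. With this covariate 4218 genes were called after UVB in KO skin, 2890 of the 5666 among them, and 98 of the 5666 changed sign. The muscle score separates these groups, at 0.106 or more in KO control and -0.116 or less in KO UVB libraries. Values with this covariate therefore cannot tell muscle RNA apart from UVB in KO skin. Anagen hair follicle genes fell (20 of 23 members fell, 20 fell adjusted over the list alone), including Crym (-1.77 ± 0.27). Over the list the median was -3.93 (camera adjusted p = 2.08e-09, adjusted p = 0.28 with an estimated correlation). Hair follicle bulge stem cell genes fell (9 of 15 members fell, 11 fell adjusted over the list alone), with the stem cell keratin Krt15 at 1488 ± 395 and 564 ± 53.9 CPM (-1.40 ± 0.20) and the Hedgehog effector Gli1 (-0.80 ± 0.18). This list's median was -0.45 (camera adjusted p = 0.000729, adjusted p = 0.28 with an estimated correlation). In the Wnt pathway list (2 of 26 members rose and 11 fell, 2 rose and 12 fell adjusted over the list alone), the feedback inhibitor Axin2 (-0.73 ± 0.16), the receptor Lgr6 (-1.05 ± 0.23) and Dkk3 (-0.66 ± 0.15) fell. The median was -0.42 (camera adjusted p = 0.0115, adjusted p = 0.547 with an estimated correlation). The muscle covariate moved these 3 to -1.16, -1.85 and -1.15. The Schwann and nerve list fell (7 of 15 members fell, 7 fell adjusted over the list alone), with Cdh19 (-0.75 ± 0.14). Here the median was -0.50 (camera adjusted p = 0.000602, adjusted p = 0.323 with an estimated correlation). Of 17 melanocyte genes 2 rose and 3 fell (median -0.03, camera adjusted p = 0.976, adjusted p = 0.992 with an estimated correlation). Mitf (-0.32 ± 0.12, adjusted p = 0.0455) and Sox10 (-0.50 ± 0.15, adjusted p = 0.0165) were among those that fell, while Kit (-0.20 ± 0.12), Dct (-0.10 ± 0.27), Tyr (0.52 ± 0.49) and Pmel (0.13 ± 0.28) did not pass. The Mitf call ended without KO control library 2 (adjusted p = 0.175), 3 (0.0571) or 4 (0.0755) or KO UVB library 1 (0.138), 2 (0.0765) or 3 (0.099), within 0.0218 to 0.789 over all alternatives, and its log2 fold change was -0.21 without KO control library 2. The Sox10 call ended without KO control library 2 (0.0662) or 3 (0.0644) or KO UVB library 1 (0.0513), within 0.0026 to 0.303.

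The inflammatory cytokine genes Il1b (3.10 ± 0.81, adjusted p = 0.0093) and Il6 (3.33 ± 0.83, adjusted p = 0.00678) rose after UVB in KO skin, and both rested in size on KO UVB library 3. That library held 78.2 CPM of Il1b against 3.38 to 8.79 in the other 3, and 7.16 CPM of Il6. Without it the log2 fold change was 1.11 for Il1b (adjusted p = 0.0462) and 1.49 for Il6 (0.0213), and without libraries 3 and 4, added after seeing the data, Il1b was at 0.72 and no longer called (0.199). Adjusted p ran from 0.000521 to 0.339 for Il1b and from 0.00226 to 0.219 for Il6 over all alternatives. In WT skin, Il1b (1.61 ± 0.83, adjusted p = 0.189) and Il6 (2.53 ± 1.14, adjusted p = 0.136) did not pass the test. The difference between the genotypes did not pass for Il1b (1.49 ± 1.14, adjusted p = 0.61) or Il6 (0.80 ± 1.77, adjusted p = 0.881).

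Of 6712 genes called after UVB in either genotype, 2244 were called in both. Across 17531 genes, which are not independent replicates, the log2 fold changes in WT and KO had a Pearson correlation of 0.745 and a Spearman correlation of 0.596, with 73.9% of genes of the same sign. Among calls, 1380 genes were higher in both, where independent lists would share 306, and 855 were lower in both, where they would share 228. Called higher in WT and not higher in KO were 402 genes, and 1631 were higher in KO and not higher in WT. Called lower in WT and not lower in KO were 653, and 1800 were lower in KO and not lower in WT. These counts include the genes called in opposite directions given below, and a call in 1 genotype alone does not show that the effects differ. The pair of comparisons has no library in common. Of the called genes, 3 higher in WT were lower in KO and 6 lower in WT were higher in KO. The interaction test, which asks whether the UVB effect differs between genotypes, called 4 genes, with 2238 at an unadjusted p under 0.05. Hba-a2 (6.74 ± 0.74, adjusted p = 0.00255) fell after UVB in WT and stayed at 13.7 CPM in KO UVB skin. Pinlyp, a phospholipase inhibitor gene (2.53 ± 0.31, adjusted p = 0.00458), was at 17.9 and 10.8 CPM in WT control and UVB skin and at 3.90 and 13.6 in KO. Tnik, a kinase of Wnt signalling, was lower after UVB in KO relative to WT (-0.74 ± 0.10, adjusted p = 0.0113), a call that ended without WT UVB library 2 (0.0574), 3 (0.0607) or 4 (0.0527) or KO control library 4 (0.0935), within 5.18e-07 to 0.0935 over all alternatives. Angptl8, a lipoprotein lipase inhibitor (4.69), is named here after its values were seen, to complete the 4. Krt6a, with an interaction of 2.64 ± 0.58, did not pass (adjusted p = 0.109) and was called by DESeq2 and limma voom (0.00647 and 0.00756, within 0.000103 to 0.387 over all alternatives). The count of interaction genes was 7 without WT control library 3, 30 without KO control library 1, 2 without KO control library 4, 7 without KO UVB library 1 and 110 without KO UVB library 4. It was 212 with DESeq2, 459 with limma voom, 419 with the muscle score as a covariate and 67 without KO UVB libraries 3 and 4.

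Between the genotypes, camera called 10 lists for a different UVB effect, 7 with a higher and 3 with a lower effect in KO, and each call was lost with an estimated correlation. In 9 of the 10, edgeR called 0 of 186 genes, with 30 higher and 17 lower at an unadjusted p under 0.05 (0 of 28 for proliferation), where DESeq2 called 6 higher and 3 lower and limma voom 9 and 5. The median interaction was 1.37 for neutrophil genes (camera adjusted p = 0.00157, adjusted p = 0.672 with an estimated correlation), 0.89 for monocyte and macrophage genes (4.76e-06, adjusted p = 0.744 with an estimated correlation) and 1.23 for alarmins (0.006, adjusted p = 0.744 with an estimated correlation). It was 0.34 for stress keratinocyte genes (0.00281, adjusted p = 0.792 with an estimated correlation), 0.28 for proliferation genes (0.00395, adjusted p = 0.818 with an estimated correlation) and 0.65 for anagen hair follicle genes (6.42e-10, adjusted p = 0.672 with an estimated correlation), whose level was already lower in KO control skin. The erythrocyte list, which holds Hba-a2, was at 0.55 (0.00157, adjusted p = 0.672 with an estimated correlation). Lower in KO were skeletal muscle (-0.73, 2.41e-08, adjusted p = 0.672 with an estimated correlation), epidermal terminal differentiation (-0.30, 0.00157, adjusted p = 0.792 with an estimated correlation) and hair follicle bulge stem cell genes (-0.23, 0.0334, adjusted p = 0.744 with an estimated correlation). Without WT control library 3, 17 lists were called, without KO UVB library 1, 19, and without KO UVB library 2, 17.

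**Figure D3:**
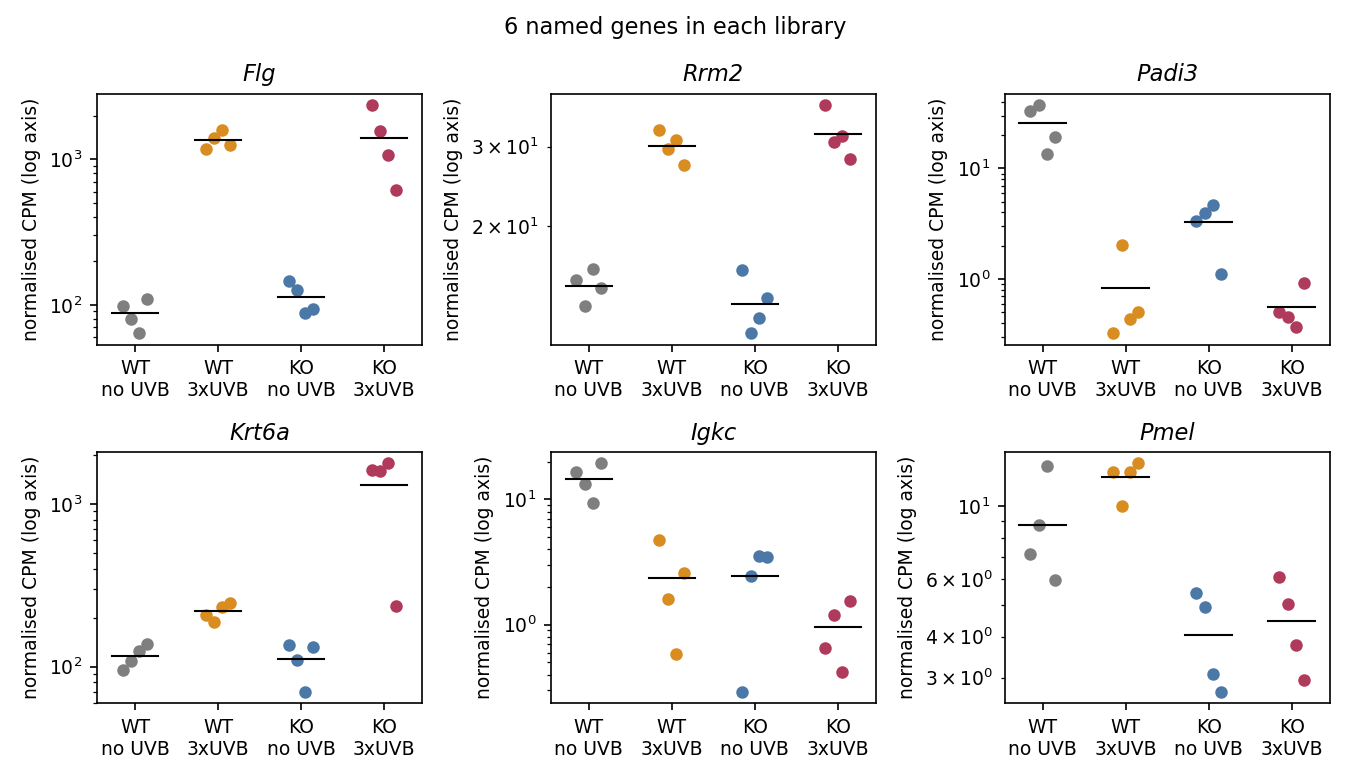
Normalised CPM on a log axis of Flg, Rrm2, Padi3, Krt6a, Igkc and Pmel in each library of the 4 groups, with each point 1 library and the black line the mean (n = 4). KO UVB library 4 is the low point of Krt6a in its group, at 237 CPM, and Padi3 and Igkc are lower in KO control than in WT control skin.

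Without UVB, KO skin held less hair follicle transcript than WT skin. The hair genes S100a3 (-2.76 ± 0.37, adjusted p = 0.00119), Krt28, an inner root sheath keratin (-2.82 ± 0.43, adjusted p = 0.00287), and Krtap14, a keratin-associated protein (-3.54 ± 0.62, adjusted p = 0.00709), fell. Crym went from 17.2 ± 4.74 to 4.37 ± 1.27 CPM (-1.96 ± 0.24, adjusted p = 0.000578). Higher in KO were Rbp7, a retinoid-binding protein (2.43 ± 0.35, adjusted p = 0.00222), the immediate early transcription factor Fosb (3.68 ± 0.65, adjusted p = 0.00797), and Eno1b, a near-identical copy of the glycolytic gene Eno1 (6.83 ± 0.50, adjusted p = 2.36e-06), for which reads may be split between the copies. Rab6b, a Golgi trafficking GTPase (-4.24 ± 0.34, adjusted p = 7.2e-06), and Aadacl4, a lipase-like gene (-3.44 ± 0.32, adjusted p = 3.93e-05), fell. The test called 297 genes, 73 higher and 224 lower, with 218 beyond 2-fold. The groups did not overlap in 292 of the calls and in 7.68% of all genes tested, where chance gives 2.86%. Without WT control library 1 the count was 166, without WT control library 2 it was 161, without KO control library 3 it was 196 and without KO control library 4 it was 163. It was 452 with DESeq2, 589 with limma voom, 93 with a mean count filter of 100 and 6 with the anagen score as a covariate, which was added after seeing the data. In that last fit the 70 called genes of the hair keratin families were no longer called, and Krtap14 went to 0.45. The Fosb call ended with limma voom (2.98, adjusted p = 0.0704, within 1.33e-06 to 0.924 over all alternatives).

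Camera called 14 lists in KO against WT control skin, 5 higher and 9 lower, and the anagen hair follicle and melanocyte lists held with an estimated correlation. Anagen hair follicle genes fell (16 of 23 members fell, 23 fell adjusted over the list alone, median log2 fold change -3.08, camera adjusted p = 2.28e-30, adjusted p = 0.048 with an estimated correlation). The mean list score was 1.33 in WT and 0.14 in KO control libraries. The melanocyte lineage and pigmentation list was lower. The median was -0.33 (camera adjusted p = 4.03e-05, adjusted p = 0.048 with an estimated correlation). Adjusted over the list alone 9 of its 17 members fell, and over all genes edgeR called 0, with 10 lower at an unadjusted p under 0.05, DESeq2 1 and limma voom 2. Its members Pmel (-1.11 ± 0.28, adjusted p = 0.0575), Tyr (-1.46 ± 0.46, adjusted p = 0.167), Tyrp1 (-0.89 ± 0.33, adjusted p = 0.292) and Dct (-0.69 ± 0.26, adjusted p = 0.304) did not pass on their own. Mitf was at -0.04 ± 0.12. The melanosome gene Mlana leaned the other way and was not called, at 63 to 91 reads in WT control libraries. KO control library 1 held 51 Mlana reads and the other KO control libraries 117 to 136. The B and plasma cell list was lower (2 of 6 members fell, 2 fell adjusted over the list alone, median log2 fold change -0.33, camera adjusted p = 0.029, adjusted p = 0.579 with an estimated correlation). Igkc fell from 14.7 ± 4.38 to 2.45 ± 1.53 CPM (-2.59 ± 0.58, adjusted p = 0.0315), and Jchain fell (-2.85 ± 0.59, adjusted p = 0.0188). The Igkc call ended without WT control library 1 (adjusted p = 0.0871), 2 (0.0701) or 4 (0.0968) or KO control library 2 (0.083), 3 (0.0611) or 4 (0.0641), within 0.0064 to 0.853 over all alternatives. The Jchain call ended without WT control library 1 (0.0653) or 4 (0.0556) or KO control library 2 (0.0616), within 0.000289 to 0.801.

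The Schwann and nerve list was lower in KO control skin (1 of 15 fell, 2 fell adjusted over the list alone, median log2 fold change -0.26, camera adjusted p = 0.00131, adjusted p = 0.613 with an estimated correlation). The erythrocyte list was lower too (1 of 8 fell, 3 fell adjusted over the list alone, median log2 fold change -0.63, camera adjusted p = 0.00139, adjusted p = 0.579 with an estimated correlation). So was the Langerhans and dendritic cell list (1 of 20 fell, 1 fell adjusted over the list alone, median log2 fold change -0.39, camera adjusted p = 0.00173, adjusted p = 0.73 with an estimated correlation). The single dendritic cell gene was Flt3 (-0.65 ± 0.13, adjusted p = 0.0157), whose call ended without WT control library 1 (0.0653), KO control library 1 (0.0561) or 4 (0.0645), within 0.000289 to 0.924 over all alternatives. Also lower were T and NK cell (median log2 fold change -0.37, camera adjusted p = 0.00553, adjusted p = 0.753 with an estimated correlation) and cell cycle genes (median log2 fold change -0.14, camera adjusted p = 0.0224, adjusted p = 0.889 with an estimated correlation). TNF receptor pathway genes were lower (median log2 fold change -0.06, camera adjusted p = 0.0313, adjusted p = 0.715 with an estimated correlation), and the 2 of 22 pathway members that fell were Tnfrsf1a and Tnfrsf1b themselves (2 fell adjusted over the list alone). Higher were immediate early and heat shock genes (1 of 20 rose, 4 rose and 1 fell adjusted over the list alone, median log2 fold change 0.17, camera adjusted p = 0.00488, adjusted p = 0.715 with an estimated correlation) and epidermal terminal differentiation (median log2 fold change 0.33, camera adjusted p = 0.000383, adjusted p = 0.715 with an estimated correlation). So were skeletal muscle (median log2 fold change 0.34, camera adjusted p = 0.000383, adjusted p = 0.715 with an estimated correlation), dermal fibroblast and matrix (median log2 fold change 0.22, camera adjusted p = 0.000383, adjusted p = 0.613 with an estimated correlation) and adipocyte genes. Its median was 0.14 (camera adjusted p = 0.0205, adjusted p = 0.831 with an estimated correlation). KO control library 1 carried the most skeletal muscle transcript of all 16 libraries, with a list score of 1.85. Among the 155 genes of the 7 called lists in which edgeR called 0 genes, 13 were higher and 17 lower at an unadjusted p under 0.05, DESeq2 called 2 higher and 2 lower and limma voom 3 higher and 4 lower.

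With UVB, KO skin held more of the stress keratin gene Krt6a than WT skin and less of the keratin gene Krt2. Krt6a was at 1308 ± 719 CPM in KO UVB against 218 ± 24.8 in WT UVB skin (2.58 ± 0.43, adjusted p = 0.00911), although KO UVB library 4, at 237 CPM, stood apart from its group. A fit of the 2 groups alone did not call Krt6a (2.58, adjusted p = 0.0877, within 4.99e-07 to 0.0877 over all alternatives). The epidermal keratin Krt2 (-3.46 ± 0.46, adjusted p = 0.00121) and the membrane receptor gene Paqr7 (-1.68 ± 0.22, adjusted p = 0.000886) fell. As without UVB, Eno1b (9.21 ± 0.53, adjusted p = 9.89e-08) and Rbp7 (2.46 ± 0.34, adjusted p = 0.00153) rose. Again Rab6b (-3.83 ± 0.35, adjusted p = 3.07e-05) and Aadacl4 (-2.34 ± 0.30, adjusted p = 0.000886) fell, as did the zinc finger genes Zfp984 (-1.99 ± 0.16) and Zfp991 (-2.26 ± 0.31), which have near-identical relatives. Hba-a2 was also higher (7.21 ± 0.61, adjusted p = 1.28e-05). The test called 150 genes, 87 higher and 63 lower, with 79 beyond 2-fold. Higher calls were the fewer with library totals (65 and 92), in a fit of the 2 groups alone (34 and 45), with the muscle score as a covariate (602 and 696) and with a mean count filter of 100 (51 and 54). The groups did not overlap in 144 of the calls and in 8.16% of all genes tested, where chance gives 2.86%. Without WT UVB library 1, 2 or 4 the count was 63, 59 or 62, and without KO UVB library 1, 2, 3 or 4 it was 454, 70, 76 or 487. It was 658 with DESeq2, 1117 with limma voom, 1298 with the muscle score as a covariate and 79 in a fit of the 2 groups alone. Added after seeing the data, the anagen score as a covariate gave 62 and the fit without KO UVB libraries 3 and 4 gave 313.

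Camera called 12 lists in KO against WT UVB skin, 7 higher and 5 lower, each lost with an estimated correlation, and 20 without KO UVB library 1. Stress and wound keratinocyte genes were higher (3 of 24 rose, 15 rose adjusted over the list alone, median log2 fold change 1.25, camera adjusted p = 7.12e-08, adjusted p = 0.432 with an estimated correlation), among them the EGF receptor ligand Epgn (1.87 ± 0.36, adjusted p = 0.0254). Monocyte and macrophage genes were higher (1 of 21 rose, 13 rose adjusted over the list alone, median log2 fold change 0.67, camera adjusted p = 4.92e-07, adjusted p = 0.463 with an estimated correlation), with the Fc receptor Fcgr3 at 55.1 ± 5.88 and 117 ± 38.5 CPM (1.08 ± 0.21, adjusted p = 0.0254). The oxidative stress list was higher (1 of 16 rose, 2 rose adjusted over the list alone, median log2 fold change 0.23, camera adjusted p = 0.0022, adjusted p = 0.432 with an estimated correlation), with Gsta4 (1.60 ± 0.30, adjusted p = 0.021). Alarmins were higher (1 of 17 rose, 7 rose adjusted over the list alone, median log2 fold change 0.96, camera adjusted p = 9.67e-05, adjusted p = 0.452 with an estimated correlation). Neutrophil genes were also higher (7 rose adjusted over the list alone, median log2 fold change 1.51, camera adjusted p = 1.34e-05, adjusted p = 0.432 with an estimated correlation). The same held for matrix proteases (6 rose adjusted over the list alone, median log2 fold change 0.54, camera adjusted p = 0.00226, adjusted p = 0.452 with an estimated correlation) and for immediate early genes (1 rose adjusted over the list alone, median log2 fold change 0.25, camera adjusted p = 0.00504, adjusted p = 0.671 with an estimated correlation). KO UVB library 3 had the highest score of all 16 libraries in each of these 7 lists, such as 1.81 for neutrophils and 1.63 for monocytes and macrophages. In the monocyte and macrophage score KO UVB library 1, at -0.684, lay within the range of WT UVB libraries, -1.13 to -0.161. The Epgn call ended without WT UVB library 1 (adjusted p = 0.075), 2 (0.0916) or 4 (0.0667), and its log2 fold change was 1.19 without KO UVB library 3. The Fcgr3 call ended without WT UVB library 1 (0.0573), 2 (0.0902) or 4 (0.0674) or KO UVB library 2 (0.0716). The Gsta4 call ended without WT UVB library 1 (0.0576), 2 (0.0697) or 4 (0.0654) or KO UVB library 3 (0.0539). Over all alternatives adjusted p ran from 5.11e-05 to 0.135 for Epgn, from 8.81e-05 to 0.108 for Fcgr3 and from 3.39e-05 to 0.0697 for Gsta4.

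The melanocyte lineage and pigmentation list was lower in KO UVB than in WT UVB skin (1 of 17 fell, 1 rose and 3 fell adjusted over the list alone, median log2 fold change -0.38, camera adjusted p = 0.00353, adjusted p = 0.432 with an estimated correlation). Pmel, the melanosome matrix protein gene, fell from 12.2 ± 1.53 to 4.46 ± 1.37 CPM (-1.46 ± 0.28, adjusted p = 0.0234). The genes Dct (-1.10 ± 0.27, adjusted p = 0.062), Tyr (-0.96 ± 0.44, adjusted p = 0.297), Tyrp1 (-0.61 ± 0.33, adjusted p = 0.379), Kit (-0.10 ± 0.12) and Mitf (0.13 ± 0.12) did not pass. The Pmel call ended without WT UVB library 1 (adjusted p = 0.0608) or 4 (0.0667), KO UVB library 2 (0.0573) or 3 (0.0664) and without KO UVB libraries 3 and 4 together (-1.14, 0.0895), within 8.56e-05 to 0.0895 over all alternatives. Whether UVB changed the melanocyte list differently in KO was tested by the interaction, which gave a median of 0.15 (camera adjusted p = 0.509). Also lower in KO UVB skin were skeletal muscle (3 fell adjusted over the list alone, median log2 fold change -0.42, camera adjusted p = 3.6e-05, adjusted p = 0.544 with an estimated correlation) and anagen hair follicle genes (0 of 23 called, median log2 fold change -1.67, camera adjusted p = 0.0007, adjusted p = 0.671 with an estimated correlation), whose score in WT UVB library 2 was 0.0486 against -0.840 to -0.734 in its group and -1.10 to -0.748 in KO UVB libraries. Bulge stem cell genes were lower (2 fell adjusted over the list alone, median log2 fold change -0.29, camera adjusted p = 0.00153, adjusted p = 0.432 with an estimated correlation), as were Wnt pathway genes (1 fell adjusted over the list alone, median log2 fold change -0.19, camera adjusted p = 0.0022, adjusted p = 0.54 with an estimated correlation). The mean muscle score was -0.06 in WT UVB and -0.89 in KO UVB libraries. Among the 131 genes of the 7 called lists in which edgeR called 0 genes, 21 were higher and 25 lower at an unadjusted p under 0.05, DESeq2 called 9 higher and 5 lower and limma voom 8 higher and 7 lower.

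Genes that differed between the genotypes clustered around Tnfrsf1b. Both KO against WT comparisons shared 21 higher genes, where independent lists would share 0.362, and 22 lower genes, where they would share 0.805. Of these 43, 21 were Tnfrsf1b itself or among the 100 tested genes on each side of it in annotation order. Aadacl4, Rbp7, Zfp984 and Zfp991 lay in this window, as did Padi3. In control skin 27 of these 200 genes were called, against 269 of 17289 elsewhere (odds ratio 9.87, two-sided Fisher's exact test across genes, p = 6.49e-17). With UVB 23 were called, against 126 elsewhere (odds ratio 17.7, two-sided Fisher's exact test, p = 1.08e-19). Of 265 other windows of this size the median held 2 calls in control skin and 95% held at most 12, while 4 held 27 or more and the highest held 42, 29 of them in hair keratin families. With UVB the highest other window held 10. The 200 genes around Tnfrsf1a held 2 calls without UVB and 1 with UVB. These counts were chosen after seeing the data, and neighbouring genes are not independent.

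**Figure D4:**
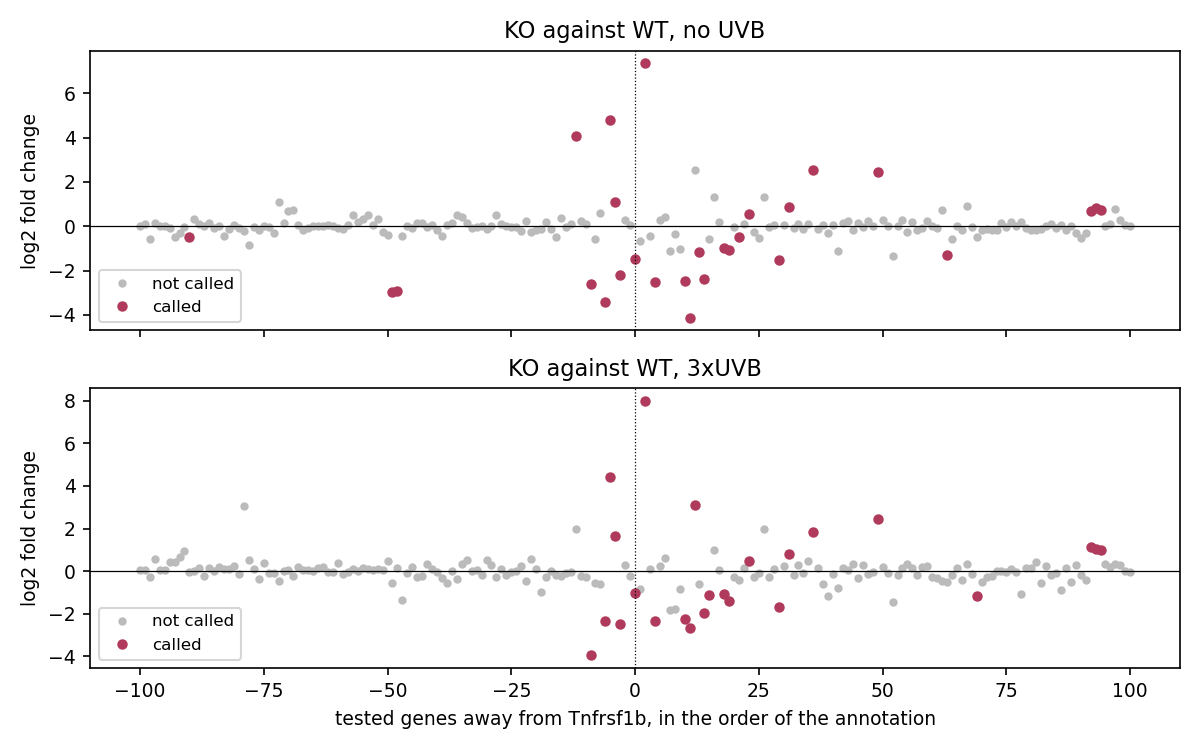
Log2 fold change, KO against WT, of the 200 tested genes around Tnfrsf1b (y axis) by their place in the annotation's order relative to it (x axis, in genes), without UVB above and with 3xUVB below, called genes in red. Called genes number 27 without UVB and 23 with UVB and lie on both sides of Tnfrsf1b.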

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

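The tests of the 3 patterns weighed below were chosen after the results were seen, while the rule for single libraries and the interaction test were fixed before. A library far from the 3 others of its group was looked for in 604 groups of values, and 40 stood out, where chance gives about 1 in 20. Of these groups 440 were single genes, with 33 of the 40. The genes were those named in the text, picked in part by their size or call in these data, and genes that vary together can stand out together.

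Genes called in KO against WT clustered next to Tnfrsf1b in both treatments. Strain DNA carried along with the knockout allele may account for this: 27 of 200 neighbours were called without UVB, where 95% of other windows held at most 12. Reads shared between near-identical zinc finger copies are argued against as the whole cause, since 15 calls were left without zinc finger and predicted genes, where 95% of other windows held at most 7. Around Tnfrsf1a 2 neighbours were called without UVB, where other windows held a median of 2 and 95% held at most 13. No cluster was seen there, and this count cannot tell whether strain DNA was carried along without changing its neighbours. An effect of the missing receptors on the genes next to Tnfrsf1b was not tested and stays open, and the sources used here give no strain of the knockout.

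Anagen hair follicle genes and the melanocyte list were lower in KO control than in WT control skin. With the anagen score as a covariate 6 of 297 calls without UVB held, and the 227 calls outside the hair keratin families went from a median of 1.63 to 0.828 (SE 0.301 to 0.515), but the score separates these groups completely, so less anagen hair follicle RNA cannot be told apart from other causes by this test. For the mean of 26 of the 27 calls next to Tnfrsf1b, without the anagen gene Padi3, that account is argued against, since a share of 0.883 (SE 0.0283) of the difference was left with UVB, where the anagen list kept 0.277 (SE 0.253), but it stays open for single members such as Padi1 (-2.92 without and 0.14 with UVB), Zbtb40 (-0.50 and -0.06) and Car6 (-1.32 and -0.51) and for the 199 calls outside this window and the hair keratin families, which kept 0.297. For the melanocyte list it stays open: the list kept 0.748 (SE 0.251), 1.32 SE from the anagen list, and the covariate decides nothing, since it took its median from -0.33 to -0.419 without UVB, where the score separates the groups, and from -0.38 to -0.344 with UVB (camera p = 0.000989, p = 0.0245 with an estimated correlation), where the median of all calls stayed near its value (1.05 and 1.04) while 58 of 150 held. A difference in hair cycle stage or in pigment cells between the genotypes was not tested and stays open, as does one in hair cycle stage between control and UVB skin.

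KO UVB library 4 held Krt6a at 237 CPM against 1598 to 1775 in the other 3, and Gsdmc at 24.8 against 93.0 to 103 CPM. An unirradiated KO library under a wrong label is argued against by its p53 list score, 0.484 against at most -0.210 in KO control libraries (SD 0.225). Fewer keratinocytes are argued against as the whole cause by Krt6a over Krt5, 0.0847 against 0.262 to 0.494 (SD 0.117). As a part of the cause they stay open, since this library was its group's lowest in Krt5 (2795 against 3590 to 6201 CPM) and in the basal keratinocyte score (-1.37 against 0.123 to 0.998). Reads taken by 1 abundant gene ID are argued against by its share of 4.09% of the reads and by Krt6a without that ID, in CPM with no TMM factor, 234 against at least 1543. A weaker or differently timed UVB response of this skin piece could be a candidate explanation and was not tested.

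WT UVB library 2 stood apart most often, in 13 of the 40. Its anagen list score was 0.0486 against -0.840 to -0.734, and the hair genes Krt72 (4.84 CPM), Krt33a (2.51), Padi3 (2.04), Krt86 (1.99), Krt81 (1.47), Krt34 (1.38), Krtap14 (1.04), Krtap11-1 (0.949), Krtap21-1 (0.569) and Krt33b (0.474) were its group's highest. It was also highest in Cdkn1a (348 against 311 to 317 CPM) and Mitf (30.5 against 26.8 to 27.2 CPM). KO UVB library 3 was highest in Il1b (78.2 against 3.38 to 8.79 CPM), Il6 (7.16 against 0.498 to 0.856 CPM), Cxcr2 (31.7 against 2.60 to 7.42 CPM) and Epgn (39.3 against 9.36 to 13 CPM). KO UVB library 4 was also highest in Fosb (25.1 against 12.2 to 13.4 CPM) and in Krt33b (0.0455 CPM, from 1 read, against 0).

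KO control library 1 was lowest in the list scores of Wnt pathway (-0.662 against 0.457 to 0.629) and basal keratinocyte genes (-0.673 against 0.323 to 0.507) and in Paqr7 (136.7 against 204 to 218 CPM), and highest in Actn3 (1125 against 424 to 513 CPM) and Mki67 (76.9 against 50.7 to 53.7 CPM). WT control library 2 was lowest in the bulge stem cell score (-0.0905 against 0.701 to 0.747) and in Elovl4 (769 against 1013 to 1039 CPM), and KO control library 2 in Elovl4 (859.6 against 998 to 1026 CPM). KO UVB library 1 was lowest in the mast cell score (-0.938 against 0.303 to 0.364). WT UVB library 1 was highest in the Schwann and nerve score (-0.280 against -0.504 to -0.487). WT UVB library 3 was lowest in reads outside genes (7.25 against 9.86 to 10.2%) and highest in Cxcr2 (5.33 against 2.18 to 2.67 CPM). WT UVB library 4 was highest in Olah (12.7 against 5.82 to 6.51 CPM) and Tyrp1 (24.4 against 11.1 to 12.9 CPM). WT control library 4 was highest in Serpinb3b (23.1 against 4.53 to 7.69 CPM) and Spink7 (0.0896 CPM, from 2 reads, against 0), WT control library 1 in Mmp8 (0.447 against 0.218 to 0.248 CPM), and KO UVB library 2 in Vsig4 (11.1 against 7.20 to 7.80 CPM) and Slc4a1 (0.114 CPM, from 2 reads, against 0).

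The interaction test called Hba-a2 (6.74), Angptl8 (4.69), Pinlyp (2.53) and Tnik (-0.74) for a UVB effect that differs between the genotypes. Of 100 splits, the real one included, 7 called as many genes, so chance cannot be excluded. Hba-a2, whose reads a near-identical copy can take, held 1 to 3 reads in WT UVB libraries and 168 to 471 in KO UVB libraries. By camera, median differences of called lists were 1.37 (neutrophil), 1.23 (alarmins), 0.89 (monocyte and macrophage), 0.65 (anagen hair follicle), 0.55 (erythrocyte), 0.34 (stress keratinocyte), 0.28 (proliferation), -0.73 (skeletal muscle), -0.30 (epidermal terminal differentiation) and -0.23 (bulge stem cell), each lost with an estimated correlation (adjusted p = 0.672 to 0.818).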

How the results depend on the processing

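The anagen score covariate and the fit without KO UVB libraries 3 and 4 were chosen after seeing the data, and the other alternatives before. Over 239 named gene results under all alternatives, 4305 of 4765 values kept their direction and side of the threshold, 358 lost the call, 36 gained it, 59 moved and 7 changed direction. Of the named calls, 49 of 53 held in every fit without 1 library for UVB in WT, 61 of 63 for UVB in KO, 12 of 27 for KO against WT without UVB, 12 of 23 with UVB and 2 of 3 for the interaction. At this depth and number of libraries, 69.7% of simulated changes of 1 on the log2 scale were recovered for UVB in WT and 53% for the interaction. Far fewer genes were changed in the simulation than were called for UVB in WT, so this is not the recovery of that real test.

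Genes called were 3290 for UVB in WT, 5666 for UVB in KO, 297 for KO against WT without UVB, 150 with UVB and 4 for the interaction. DESeq2 gave 452 for KO against WT without UVB, 658 with UVB and 212 for the interaction, and limma voom gave 5117 for UVB in WT, 589, 1117 and 459. A mean count of at least 100 gave 93 for KO against WT without UVB, where fewer genes are tested. No filter gave 22 for the interaction. The fit of the 2 groups alone gave fewer calls for UVB in KO (3506) and for KO against WT with UVB (79). It gave more for UVB in WT (4363) and for KO against WT without UVB (313). The muscle covariate gave 4218 for UVB in KO, with 2890 of the 5666 calls kept and 98 of the 5666 with the other sign, 1298 for KO against WT with UVB and 419 for the interaction. The muscle score separates KO control from KO UVB libraries, so for UVB in KO this fit cannot tell muscle RNA apart from UVB. Without KO UVB libraries 3 and 4 the count was 313 for KO against WT with UVB and 67 for the interaction. The anagen covariate gave 1 for UVB in WT, 319 for UVB in KO, 6 and 62 for KO against WT without and with UVB, and 0 for the interaction in edgeR (1698 at an unadjusted p under 0.05, not run in other tools). Where no reason is given, the cause was not tested.

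Without 1 library the counts ran from 2039 to 3099 for UVB in WT, 4280 to 6350 for UVB in KO, 161 to 288 for KO against WT without UVB, 59 to 487 with UVB and 2 to 110 for the interaction, and called lists from 12 to 16, 14 to 17, 11 to 16, 12 to 20 and 9 to 19. With an estimated correlation camera called 0 lists for UVB in WT (5 at an unadjusted p under 0.05), 0 for UVB in KO (3), 2 for KO against WT without UVB, 0 with UVB (2) and 0 for the interaction (0), and fry called 11, 15, 2, 0 (8 at an unadjusted p under 0.05) and 0 (5). The anagen covariate gave 8 lists for KO against WT without UVB. The exact permutation of list scores left 0 lists after adjustment, with 11, 11, 5 and 2 at a p under 0.05 in the comparisons of 2 groups.

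The sample numbers do not pair the libraries: 3 of 24 correlations between libraries of the same number, after removing the group means, were over 0.1 (-0.403 to 0.219), and 4 of 16 libraries correlated best with their own number. Taking the number as a block gave 2696, 5169, 240, 77 and 7 calls. With this block Tnfrsf1b in KO against WT with UVB was at -1.01 and not called (adjusted p = 0.0655, 0.000379 to 0.0946 over all alternatives). It was also not called with no filter (-1.02), with the anagen covariate (-0.99) or in the fit of the 2 groups alone (-1.03), and without 1 library it ran from -1.23 to -0.90. Without UVB the anagen covariate left Tnfrsf1a at -0.59 (adjusted p = 0.464, 1.95e-21 to 0.464 over all alternatives) and Tnfrsf1b at -1.34 (0.739, 4.05e-09 to 0.739), both not called. The 7 values that changed direction are hair genes under the anagen covariate, a score that holds hair genes itself: Krtap11-1 for UVB in WT (0.36), and for KO against WT without UVB Krtap9-1 (0.00583), Krtap14 (0.45), Krtap15 (1.40), Krt72 (1.10), Krtap4-6 (0.24) and Krt26 (0.98). With library totals in place of TMM the share of higher calls fell from 54.2 to 34.2% for UVB in WT, from 53.1 to 40.5% for UVB in KO and from 58.0 to 41.4% for KO against WT with UVB. The agreement of the UVB response was 0.745 over all genes, 0.836 over genes called in either genotype and 0.781 over genes with a mean count of at least 100. The combined table of the series was not run, since its columns carry no sample names.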

Other observations

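The tests of other splits, the added clock and glucocorticoid lists and the genes named beside them were chosen after the comparisons were seen, while the lists of the first paragraph were fixed before. After UVB in KO skin, genes of several lists that camera did not call moved in both directions or in part. Of 18 melanocyte niche signals, the ligands and receptors that act on pigment cells, 1 rose and 7 fell (4 rose and 7 fell adjusted over the list alone, median -0.34, camera adjusted p = 0.191), and Tgfb2, which encodes a transforming growth factor beta, fell (-0.69 ± 0.18, adjusted p = 0.0103, with a call that ended in the fit of the 2 groups alone, adjusted p = 0.0503, 0.00154 to 0.284 over all alternatives). Of 24 NF-kB target genes, 6 rose and 1 fell (the same numbers adjusted over the list alone, median 0.21, camera adjusted p = 0.324). Of 22 T and NK cell genes 3 rose and 6 fell (median -0.08, camera adjusted p = 0.146), and of 17 matrix protease genes 4 rose and 1 fell (median 0.40, camera adjusted p = 0.175). Of 76 genes in the 6 lists in which edgeR called 0 genes (interferon, B and plasma cell, mast cell, endothelial, erythrocyte and mitochondrially encoded), 4 were higher and 4 lower at an unadjusted p under 0.05, DESeq2 called 3 higher and 1 lower and limma voom 8 higher and 4 lower.

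In KO against WT control skin, 2 of 4 clock genes that peak with Arntl were called, 1 of 7 that peak with Nr1d1 and 1 of 15 glucocorticoid targets, all lower (camera p = 0.0237, 0.743 and 0.541, and 0.149, 0.878 and 0.809 with an estimated correlation). The single genes below were named after their values were seen and with no alternatives run. The clock repressor genes Cry1 (-1.18 ± 0.18, adjusted p = 0.00299) and Per2 (-0.88 ± 0.17, adjusted p = 0.0157) and the transcription factor Nfil3 (-0.94 ± 0.21, adjusted p = 0.026) fell, as did Fkbp5, a chaperone induced by glucocorticoids (-1.63 ± 0.19, adjusted p = 0.000411), and Zbtb16 (-1.30 ± 0.21, adjusted p = 0.00373), both outside the added lists. With UVB, Fkbp5 was at -0.04 ± 0.19 (adjusted p = 0.939) and its interaction did not pass (1.59 ± 0.27, adjusted p = 0.0576). Collection at different times of day was tested as a hypothesis: genes of the Arntl phase differed from those of the Nr1d1 phase by -0.445 in mean log2 fold change (-0.41 and 0.03), with an exact permutation p of 0.27 across genes, two-sided. The lists left out Arntl (-0.01 ± 0.18), Nr1d1 (1.25 ± 0.37), Dbp (0.59 ± 0.32) and Per1 (0.37 ± 0.19), none of them called. Nr1d1, Dbp and Per1 lie above the mean of the Nr1d1 phase list, so collection time stays open. Lower glucocorticoid signalling was tested by the median log2 fold change of its target genes, which was 0.0175, with members on both sides of 0. That list left out Fkbp5 and Zbtb16, and also Hif3a (-1.39 ± 0.25, adjusted p = 0.00709) and Tsc22d3 (-0.30 ± 0.21, adjusted p = 0.703). These left-out targets all lie below the list median, so lower glucocorticoid signalling stays open. Neither value reached the bound set before its test, 0.5 for the clock difference and -0.3 for the median.

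For each comparison the libraries were also split in every other way into 4 and 4 (35 splits, the real one included), and for the interaction in 100 drawn splits. For UVB in WT 1 of 35 splits, the real one, called as many genes (3290, highest other 4), and for UVB in KO 1 (5666, highest other 826). For KO against WT it was 1 without UVB (297, highest other 1) and 1 with UVB (150, highest other 77). No other split reached these counts. Still, 1 of 35 is the smallest share such splits can give, and every other split mixes the real groups, which adds spread, so chance is not excluded. For the interaction 7 of 100 splits called as many as 4 genes (highest other 13), and chance cannot be excluded. List counts were reached by other splits: 16 of 35 for UVB in WT (12, highest other 16), 23 for UVB in KO (14, highest other 21), 3 for KO against WT without UVB (14, highest other 16), 27 with UVB (12, highest other 21) and 81 of 100 for the interaction (10, highest other 20), so this count does not exclude chance for the lists. Splits that move 1 library keep part of the real difference, and among the 18 that move 2 the highest list count was 12 for UVB in WT, 17 for UVB in KO, 12 for KO against WT without UVB and 17 with UVB.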
